A study of Mus musculus with 39 samples.

How the data were processed

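RNA from snap-frozen livers of 39 male mice was sequenced, in 4 groups of wildtype chow (n = 5), knockout chow (n = 4), wildtype Western diet (n = 15) and knockout Western diet (n = 15). Per the labels, libraries were made with the NEBNext Ultra kit and read in pairs on a NovaSeq instrument. The deposited table holds raw counts per gene, made by the authors from reads aligned to GRCm39 with STAR 2.7.8a and counted with featureCounts 2.0, with FastQC and MultiQC for quality. The annotation release and the strand setting are not given in the labels used here. The counts were checked to be whole numbers from 0, with library totals between 8578865 and 30438808. Of 55416 gene identifiers, 52083 had a symbol in the annotation at hand, and these hold 99.4% of all counts. Neighbours of a gene come from a GRCm38 annotation and are used for names and order alone.

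Genes were kept by filterByExpr of edgeR 4.0.16 by group (minimum count 10, minimum total 15), which left 15296 genes, or 15461 without the 4 libraries that stood with the other diet. Libraries were scaled by TMM, and 1 quasi-likelihood model with a term per group was fitted to all 39 libraries (estimateDisp and glmQLFit with robust estimation, glmQLFTest) in R 4.3.3. The SE of a log2 fold change is the one implied by its F statistic. Adjusted p values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05, and CPM values are counts per library total as scaled by TMM, from the cpm function of edgeR, with means ± SD over mice. A log2 CPM uses a prior count of 2. Permutation tests of Cd163 were 2-sided, exact for chow and with 100000 resamples for Western diet (Python 3.11.15, scipy 1.17.1, numpy 2.4.6). Intervals for counts are exact Poisson intervals at 95%, on counts summed over the libraries of a genotype and divided by their raw totals, without TMM. They cover counting error alone, since reads without molecular identifiers are not independent molecules.

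The 5 comparisons are genotype on Western diet, genotype on chow, diet in wildtype mice, diet in knockout mice and the interaction. The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Cd163, then the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold at a mean of at least 1 CPM and with a symbol that is not a predicted gene name. It also names the 4 members with the smallest p of each list that passes or has at least 3 members called. Where fewer than 12 genes pass, it names all of them and the 6 with the smallest p that do not. Genes outside the rule were chosen after their values were seen: Hp, Hmox1, the neighbours of Cd163 and those of the closing observations.

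The 30 gene lists cover lipid, bile acid, sugar and drug metabolism, sex-biased liver genes, Kupffer cells, other macrophages, lymphocytes, neutrophils, stellate, endothelial, bile duct, red blood, fat and pancreas cells, inflammation, interferon, acute phase, stress, antioxidant, cell cycle, clock and immediate early genes, iron handling and scavenger receptors. They hold 539 genes, 14 of them in more than 1 list. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 30 lists of a comparison. Members were also counted by the gene test, adjusted over the list alone. On simulated data with known changes, the fit was tested for recovery and for the direction of camera.

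The alternatives were RLE size factors, DESeq2 1.42.0, limma voom with sample quality weights, no filter on low counts, the replicate letter as a block, the library number as a covariate, only the groups compared, each library left out in turn, camera with an estimated correlation and fry. The labels do not say that replicate letters mark pairs of mice, so no pairing was used in the reported fit. On Western diet, wildtype and knockout libraries of the same letter had a mean correlation of -0.0104. Alternatives added after the data were seen were the fit without 4 libraries, wildtype Western diet L and M summed to 1 library, and a permutation of list means over libraries. For each comparison, 100 splits of the compared libraries, the real one included, were fitted in the same way. No library was left out or moved to another group in the reported values. Figures were drawn with matplotlib 3.10.9. The values of 7 genes named by the rule are not reported here, and these genes were left out of the search for libraries far from the rest of their chow group.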

Results

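Liver transcriptomes were measured by RNA sequencing in 39 male mice, with 1 library per mouse. The mice were CD163 knockouts or wildtype littermates on the C57BL/6NTac background. CD163 is a receptor of macrophages that takes up complexes of haemoglobin and haptoglobin. From 6 weeks of age, the mice ate chow or a Western diet with fructose in the drinking water, for 8 weeks. The chow groups held 5 wildtype and 4 knockout mice, and the Western diet groups held 15 mice of each genotype. The total count per library lay between 8578865 and 30438808, with a median of 14573193. By group it was 12146027 to 18721406 in wildtype chow, 11410535 to 17816848 in knockout chow, 11021915 to 18909180 in wildtype Western diet and 8578865 to 30438808 in knockout Western diet libraries. Of 55416 genes in the table, 15296 were tested. The 37 mitochondrial genes of the table had 0 counts in every library, so no mitochondrial share can be given. The counts refer to the mouse assembly GRCm39 and the annotation at hand to GRCm38, so genes are named by symbol and identifier without coordinates.

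The genotype labels held for Cd163 in every library, whereas 4 libraries stood with the mice of the other diet. Their place was read from 189 genes called at 2-fold or more between the diets in the other 35 libraries, on a scale with the chow mean at 0 and the Western diet mean at 1. Wildtype chow A was at 0.951 and knockout chow D at 0.930, whereas the other 7 chow libraries lay between -0.0598 and 0.0788. Wildtype Western diet A was at 0.109 and knockout Western diet M at 0.0109, whereas the other 28 Western diet libraries lay between 0.845 and 1.14. The cholesterol synthesis genes placed the 4 libraries on the same sides. They are not independent of the 189 genes, since Sqle belongs to both sets. Their mean log2 CPM was 5.42 in wildtype chow A and 5.46 in knockout chow D, against 6.70 to 7.20 in the other chow libraries. It was 7.16 in wildtype Western diet A and 7.17 in knockout Western diet M, against 4.88 to 6.38 in the other Western diet libraries. The 4 libraries stayed under their labels in every test, and each count of genes is also given without them, an alternative added after the data were seen. Wildtype Western diet L and M were the closest pair of libraries, with a chi-square of 3.97 per gene against 10.4 for the next pair and 61.0 for the median pair, where sampling noise alone gives 1. They were kept as 2 mice.

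**Figure D1:**
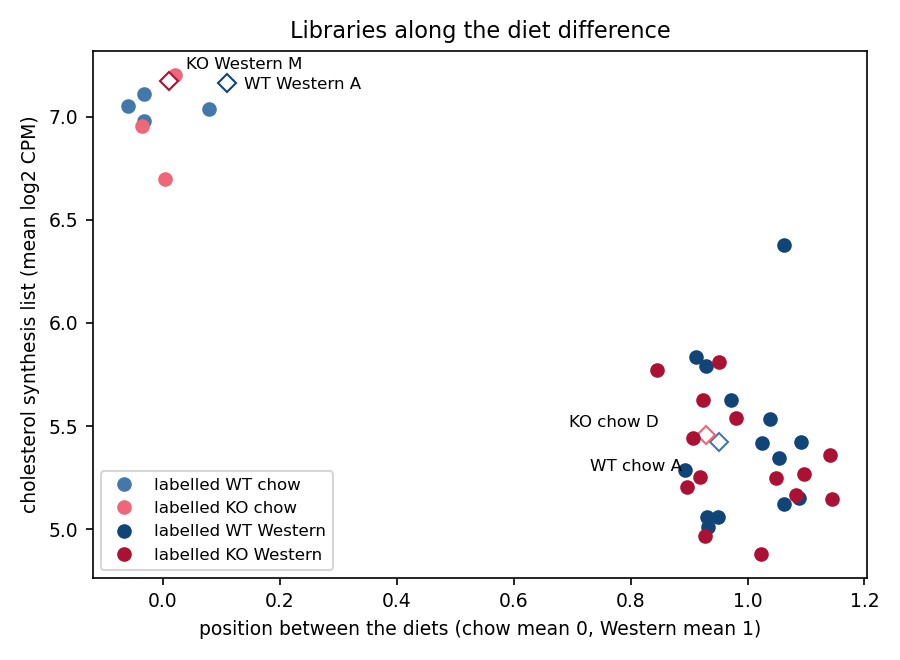
Each point is a library, placed by the diet genes on the x axis (no unit, chow mean 0 and Western diet mean 1, computed without the 4 libraries drawn as open diamonds) and by the mean log2 CPM of the cholesterol synthesis list on the y axis, coloured by its labelled group. The open diamonds of wildtype chow A and knockout chow D sit at 0.951 and 0.930, and those of wildtype Western diet A and knockout Western diet M at 0.109 and 0.0109.

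The first comparison asks what loss of CD163 does to the liver under Western diet. Cd163 (ENSMUSG00000008845), the targeted gene, was at 8.31 ± 4.27 CPM (SD, n = 15) in wildtype and at 0.354 ± 0.209 CPM (n = 15) in knockout mice, 4.27% of the wildtype level. It was lower in 15 of 15 knockout libraries than the wildtype mean. It rested on 41 to 252 counts per wildtype library and 0 to 12 per knockout library, and the 2-sided permutation p over 100000 resamples, as the doubled 1-sided p, was 2e-05, the smallest that this doubling can give. In the edgeR quasi-likelihood test its log2 fold change was -4.50 (SE 0.30, adjusted p = 1.04e-13), and no other gene passed the threshold. The genes with the next smallest p did not pass. Spic, a transcription factor of macrophages that handle iron, was at 25.7 ± 65.0 CPM in wildtype and 1.36 ± 0.832 CPM in knockout mice (adjusted p = 0.767), and 2 wildtype libraries, L and M, hold the wildtype excess. Lpl, lipoprotein lipase, was at 62.7 ± 17.7 CPM in wildtype and 104 ± 53.1 CPM in knockout mice (log2 fold change 0.73, SE 0.19, adjusted p = 0.943), higher in 13 of 15 knockout libraries. Wdr46 (log2 fold change -0.23, adjusted p = 0.427), Trat1 (-4.18, 0.537), AC133523.4 (-0.84, 0.943) and Pglyrp2, a peptidoglycan-hydrolysing protein (-0.38, 0.943), complete the 6 genes nearest to the threshold.

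Of 30 gene lists, 3 passed camera with its preset correlation on Western diet, and 0 passed with an estimated correlation. The acute phase genes, which hepatocytes express in inflammation, were lower in knockout than in wildtype mice, with a negative fold change in 24 of 24 measured members (median log2 fold change -0.48, adjusted p = 8.67e-10). The adjusted p was 0.925 with an estimated correlation and 0.890 in a permutation of list means over libraries. By gene, 0 members were called over all genes and 3 were lower adjusted over the list alone. Mt1, a metallothionein, was at 68.7 ± 92.2 CPM in wildtype and 13.8 ± 22.1 CPM in knockout mice (log2 fold change -2.32, SE 0.68, adjusted p over all genes 0.943). Wildtype Western diet F, G, L, M and N held the wildtype excess, with 141 to 305 CPM of Mt1 against at most 43.5 CPM in the other 10. The same 5 libraries had acute phase means of 8.32 to 9.72 log2 CPM and neutrophil marker means of 0.111 to 1.88. The other 10 wildtype Western diet libraries had at most 7.31 and -0.458. Mt2 (-2.73), Saa3 (-1.64) and Orm2 (-1.78) had values on the same side. The sinusoidal endothelial markers were lower as a list, with a negative fold change in 12 of 12 members but 0 of them passing by gene, over all genes or adjusted over the list alone (median -0.15, adjusted p = 1.75e-04, and adjusted p = 0.925 with an estimated correlation), with Ehd3 at -0.24, Gpr182 at -0.28, Dnase1l3 at -0.27 and Clec4g at -0.22. With the library number as a covariate, this list turned its direction (adjusted p = 0.847). Across the Western diet libraries, its mean level was lower where that of the erythroid markers was higher (Spearman's rho -0.507 over 15 wildtype and -0.686 over 15 knockout libraries, a description chosen after the data were seen). The erythroid list did not pass between the genotypes, with a median of 0.75 (adjusted p = 0.0958), so an influence of red blood cells on the endothelial difference was not excluded. The fatty acid oxidation and PPARA target list was higher, with a positive fold change in 21 of 24 members but 0 of them passing by gene, over all genes or adjusted over the list alone (median 0.13, adjusted p = 6.68e-04, and adjusted p = 0.925 with an estimated correlation). Among the wildtype Western diet libraries, G, L and M had the lowest means of this list, 5.77, 6.00 and 5.97 log2 CPM against 6.48 to 7.65 in the other 12. The mean was 6.88 in all wildtype and 7.14 in knockout libraries, and 7.12 in wildtype libraries without these 3, a description chosen after the data were seen. Leaving out the lowest libraries of the lower group alone must narrow the difference, and knockout Western diet H, at 5.94, was kept. Among the members with the smallest p were Ppara, the receptor itself (0.29), Acadl (0.12) and Fgf21 (0.72), none of which passed.

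The other 27 lists had adjusted p between 0.0680 and 0.995 on Western diet. The resident Kupffer cell markers had 15 of 19 members on the positive side and a median of 0.14, but a mean of -0.10 (adjusted p = 0.295), and 1 member, Spic, was lower adjusted over the list alone. Spic (-4.13), whose wildtype excess sat in libraries L and M, the closest pair, alone made the mean negative. Recruited and lipid-associated macrophage markers had a median of 0.23 (adjusted p = 0.245), with 1 of 17 members higher adjusted over the list alone. Without the 4 libraries, edgeR called Cd163 and 0 other genes, and 5 lists passed camera, again 0 of them with an estimated correlation. DESeq2 called 4 genes, Cd163, Spic, 1700013D24Rik and Gm44007, and limma voom called Cd163 alone, and at an unadjusted p under 0.05 edgeR had 777 of 15296 genes, 5.08%. In simulated data of this design, 60% of genes changed by 0.5 on the log2 scale and 85% of those changed by 1 were recovered. The simulation changed 200 genes at once, drew genes independently of each other and gave 11 false calls. With fewer true changes the adjusted threshold is stricter, so these shares do not say how many such changes were missed here.

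**Figure D2:**
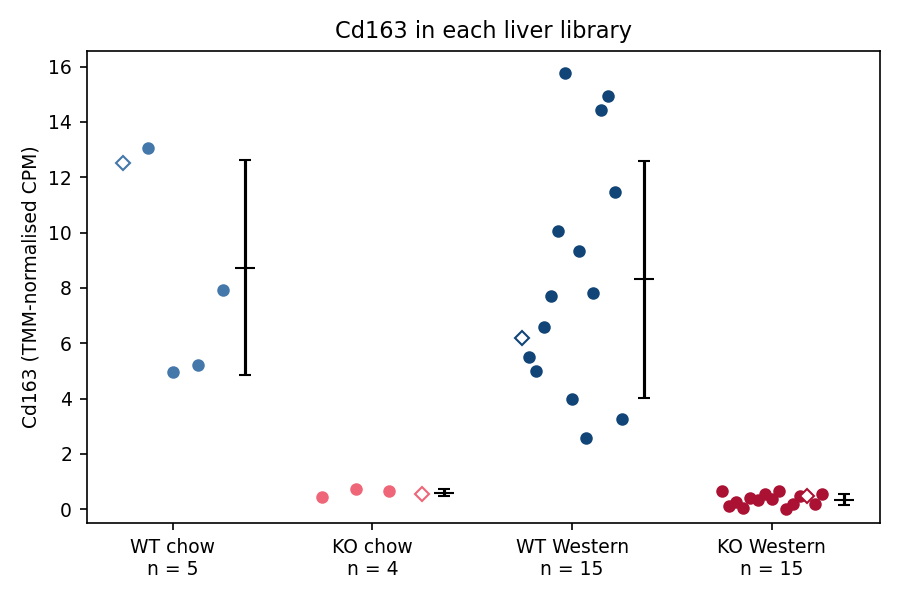
Each point is the TMM-normalised CPM of Cd163 in a library, with the mean and SD of each group in black, and open diamonds mark the 4 libraries that stood with the other diet. The knockout libraries lie at or below 0.746 CPM and the wildtype libraries at or above 2.59 CPM.

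On chow, the comparison of 4 knockout with 5 wildtype mice asks what the knockout does without the diet. Cd163 was at 8.74 ± 3.89 CPM (n = 5) in wildtype and 0.601 ± 0.138 CPM (n = 4) in knockout mice, 6.88% of the wildtype level, and lower in 4 of 4 knockout libraries. The exact 2-sided permutation p was 0.0159 over 126 splits, where the smallest possible is 0.00794. Its log2 fold change was -3.86 (SE 0.53, edgeR adjusted p = 1.27e-04), and 0 other genes passed. Limma voom gave -3.81 for Cd163, which did not pass there. BC030867 was at 0.132 ± 0.159 CPM in wildtype and 3.96 ± 4.30 CPM in knockout chow mice (log2 fold change 4.91, SE 1.33, adjusted p = 1.00), with 8.05 and 7.29 CPM in knockout chow A and C and 0.271 and 0.216 CPM in B and D. The other genes nearest to the threshold were 4931406P16Rik (0.75), Gm35570 (2.13), Star, a cholesterol carrier of mitochondria (0.71), Prtn3, a neutrophil protease (-4.98), and Gm9502 (1.45), all at an adjusted p of 1.00.

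On chow, 4 lists were lower in knockout mice by camera, and each had an adjusted p = 0.987 with an estimated correlation. The acute phase list had a negative fold change in 24 of 24 members (median -0.79, adjusted p = 1.88e-10), and 0 members were called over all genes or adjusted over the list alone. Saa1, serum amyloid A, was at 734 ± 942 CPM in wildtype and 66.5 ± 20.5 CPM in knockout chow mice (log2 fold change -3.47, SE 1.60). Its wildtype mean rested on 1397 CPM in library A and 2067 CPM in library E, against 43.5, 125 and 38.3 CPM in B, C and D. The neutrophil marker mean was 1.20 log2 CPM in wildtype chow E and -0.390 in A, against at most -0.688 in the other 7 chow libraries. Saa2 (-4.31), Lcn2 (-4.09) and Orm2 (-3.25) lay on the same side. The stellate cell and fibrosis list was lower, with a negative fold change in 21 of 26 members but 0 of them passing by gene (median -0.22, adjusted p = 0.00175), with Col4a2, a basement membrane collagen, at 49.7 ± 11.3 CPM in wildtype and 33.2 ± 8.30 CPM in knockout mice. Thbs1 (-1.19), Des (-0.44) and Col4a1 (-0.45) were its next members. The unfolded protein and integrated stress response list was lower, with a negative fold change in 14 of 19 members but 0 of them passing by gene (median -0.35, adjusted p = 0.00308), with Calr (-0.33), Pdia6 (-0.35), Pdia4 (-0.57) and Dnajb9 (-0.59), chaperones and folding enzymes of the endoplasmic reticulum. The inflammatory cytokine and chemokine list was lower, with a negative fold change in 16 of 19 members (median -0.38, adjusted p = 0.0136), with Tlr4 (-0.95), Ccl2 (-2.01), Ccl3 (-1.75) and Cxcl1 (-2.14), and 0 members passed by gene. Its level was 2.77 log2 CPM in wildtype chow A and 2.71 in E, against 1.40 to 1.84 in the other 7 chow libraries. Without wildtype chow E, the inflammatory list (adjusted p = 0.303) and the stellate cell list (adjusted p = 0.110) did not pass, and without knockout chow A the stress response list did not (adjusted p = 0.131). With 1 library left out, the inflammatory list passed in 35 of 39 fits, the stress response list in 36, the stellate cell list in 37 and the acute phase list in 39, and 2 lists passed without knockout chow D. The acute phase level was 8.37 log2 CPM in wildtype chow A and 8.46 in E. It was 6.16 to 6.61 in wildtype chow B, C and D and 6.22 to 6.54 in knockout chow libraries. Every fit with 1 library left out keeps A or E, so these fits do not test whether the acute phase call rests on them.

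The other 26 lists had adjusted p between 0.124 and 0.979 on chow. Without the 4 libraries, edgeR called Cd163 alone, and 2 lists passed camera: acute phase and stellate cell and fibrosis genes (both adjusted p = 0.00206, and 0 lists with an estimated correlation). That fit left out wildtype chow A and kept E, which then alone held the high acute phase level among the chow libraries. DESeq2 called Cd163 alone and limma voom 0 genes, and 2.74% of genes had an unadjusted p under 0.05 with edgeR. In simulated data, 13% of genes changed by 0.5 and 54% of those changed by 1 on the log2 scale were recovered. Here too the simulation changed 200 independent genes at once, so the same limit holds.

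The diet comparison in wildtype mice asks how the liver responds to Western diet. By edgeR, 118 genes were higher and 94 lower on Western diet, with genes of cholesterol synthesis among the lower ones and genes of fatty acid synthesis and fructose metabolism among the higher ones. Of 24 cholesterol synthesis and uptake genes, 6 fell and 18 did not pass, whereas 22 were lower adjusted over the list alone. Cyp51, a sterol demethylase, fell from 189 ± 81.6 CPM (n = 5) on chow to 50.5 ± 46.5 CPM (n = 15) on Western diet (log2 fold change -1.90, SE 0.45, adjusted p = 0.0317), and Msmo1 fell from 180 ± 84.7 to 43.5 ± 50.4 CPM (-2.05, SE 0.52, adjusted p = 0.0447). Nsdhl (-1.77), Mvk (-1.39) and Srebf2, the transcription factor that drives the pathway (-0.54), fell too. The list passed camera (median -1.0, adjusted p = 8.91e-20), with an adjusted p = 0.267 with an estimated correlation.

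Apoa4, an apolipoprotein of triglyceride-rich particles, had the largest rise among the genes named by rule, from 104 ± 53.1 to 999 ± 632 CPM (log2 fold change 3.26, SE 0.69, adjusted p = 0.0198), and it was above the chow mean in 14 of 15 Western diet libraries. The other largest rises were Slc2a4, an insulin-responsive glucose transporter (3.16), Dkk4, a Wnt antagonist (2.75), Smpd3, a sphingomyelinase (2.66), Grin3b, a glutamate receptor subunit (2.31), and Gpc1, a glypican (2.14). The largest falls besides sterol genes were Adgrf1, an adhesion G protein-coupled receptor, from 6.01 ± 3.59 to 1.06 ± 0.608 CPM (-2.51), Bglap3 (-1.91) and Csad, an enzyme of taurine synthesis, from 601 ± 207 to 169 ± 64.7 CPM (-1.83), each lower in 15 of 15 libraries.

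In fatty acid and triglyceride synthesis, 3 of 22 members rose and 19 did not pass. Srebf1, the main lipogenic transcription factor, rose from 367 ± 162 to 954 ± 336 CPM (log2 fold change 1.38, SE 0.29, adjusted p = 0.0198), Scd1, a fatty acid desaturase, from 5895 ± 3229 to 17620 ± 9150 CPM (1.58), and Agpat2 by 0.45. Thrsp was at 1.40 (adjusted p = 0.0623). The list passed camera (adjusted p = 1.39e-06, and adjusted p = 0.386 with an estimated correlation). In fructose and glucose metabolism, 4 of 17 members rose: Khk, the fructokinase, from 568 ± 65.2 to 970 ± 189 CPM (0.77, SE 0.17, adjusted p = 0.0198), Pklr, pyruvate kinase (1.46), Pcx, pyruvate carboxylase (0.85), and Tkfc, a triokinase (0.86). That list had an adjusted p = 2.48e-06, and an adjusted p = 0.267 with an estimated correlation. Abcg5 and Abcg8, which form a sterol exporter, rose by 1.61 and 1.36, and Abcb4, a phospholipid exporter of bile, by 0.49. Amacr was at 0.29 (adjusted p = 0.113), and the bile acid synthesis and transport list did not pass (adjusted p = 0.0870).

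Another 7 lists passed camera in wildtype mice. Lipid droplet genes rose as a list (median 0.39, 17 of 18 positive, adjusted p = 2.02e-04, and adjusted p = 0.546 with an estimated correlation), with Plin2, a lipid droplet coat protein, at 484 ± 142 and 731 ± 222 CPM (0.59, adjusted p = 0.138), Cideb (0.41), Plin5 (0.34) and Cidec (1.94). Fatty acid oxidation and PPARA targets rose as a list (23 of 24 positive, adjusted p = 4.18e-05, and adjusted p = 0.640 with an estimated correlation), with Cpt1a (0.67), Acaa1b (0.90) and Hadha (0.32), 0 of them called over all genes. Cell cycle genes rose as a list (19 of 21 positive, adjusted p = 2.32e-04, and adjusted p = 0.640 with an estimated correlation), with cyclin Ccne1 called (1.37), while Rrm2 (0.96), Mcm3 (0.60) and Mcm4 (0.49) did not pass. The interferon response list rose (18 of 23 positive, adjusted p = 0.0137, and adjusted p = 0.853 with an estimated correlation), and its 2 called members, Tap1 (0.57) and Psmb9 (0.51), serve antigen processing, whereas Psmb8 (0.33) did not pass. The circadian clock list rose (15 of 18 positive, adjusted p = 0.0137, and adjusted p = 0.386 with an estimated correlation), with 1 of 18 members called and 17 not passing, among them Cry2 (0.49), Bhlhe41 (1.08) and Clock (-0.18). The erythroid markers rose as a list (5 of 5 positive, adjusted p = 0.0398, and adjusted p = 0.640 with an estimated correlation), with Hba-a1 at 2.18 ± 2.24 CPM on chow and 8.08 ± 9.82 CPM on Western diet, Alas2 at 0.28, Hbb-bt at 1.76 and Hbb-bs at 1.49, 0 of them called. The globin copies are near identical, so the share of reads given to each is uncertain. Xenobiotic metabolism fell as a list (14 of 25 negative, adjusted p = 0.0427, and adjusted p = 0.853 with an estimated correlation), with Ces2a, a carboxylesterase, falling from 359 ± 89.6 to 217 ± 45.3 CPM (-0.73), and Cyp2c55 (-1.15), Gsta2 (-1.29) and Cyp3a11 (-1.15) not passing. With 1 library left out, the xenobiotic list passed in 27 of 39 fits (adjusted p = 0.388 without wildtype chow D), the erythroid list in 31 and the interferon and circadian lists in 38 each.

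Cd163 in wildtype mice was at -0.08 (adjusted p = 0.932) between the diets. The remaining 20 lists had adjusted p between 0.0870 and 0.883. The edgeR count of 212 genes became 1339 without the 4 libraries, 659 higher and 680 lower, with 209 of the 212 genes shared and all 209 on the same side. It also moved when 1 library at a time was left out: to 556, 0, 11, 6 and 26 without wildtype chow A, B, C, D and E, to 325 without knockout chow D, to 501 without wildtype Western diet A, and to between 85 and 140 without any of wildtype Western diet B to F, H to M and O and knockout Western diet B, D, G, I, K, L and N. With the library number as a covariate, the count was 0. DESeq2 called 512 genes and limma voom 1020.

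**Figure D3:**
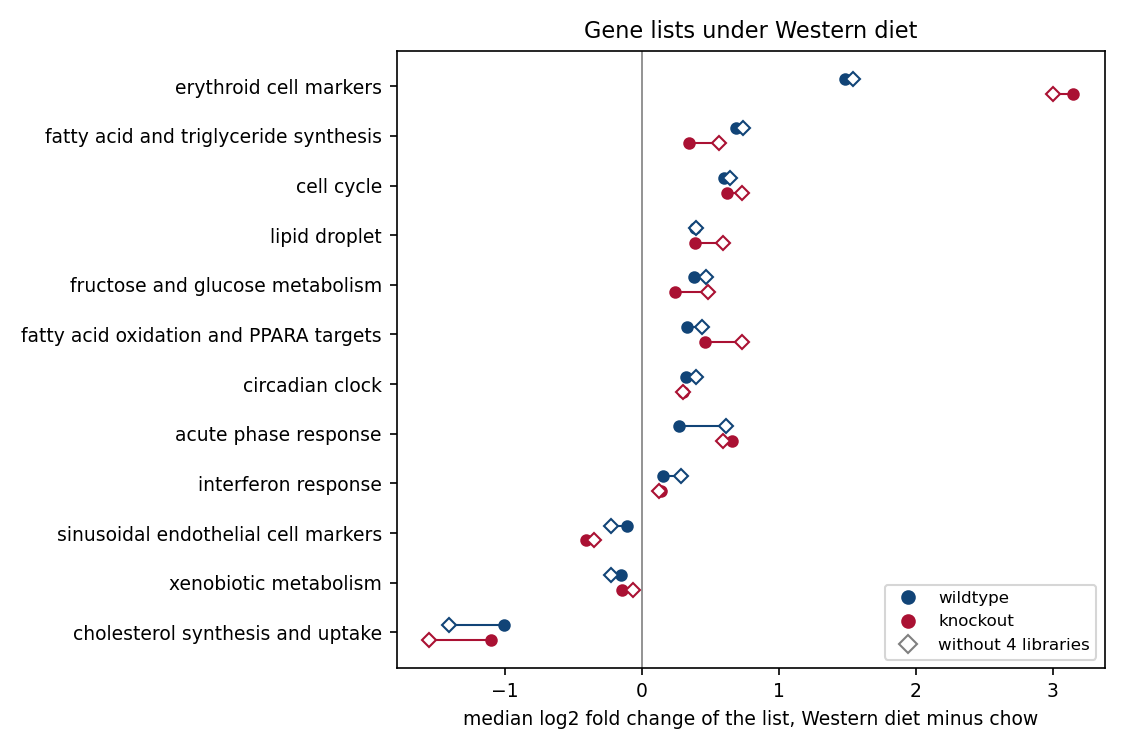
Median log2 fold change (Western diet minus chow, x axis) of each list that passed camera in wildtype or knockout mice, from all libraries (filled circles) and without the 4 libraries that stood with the other diet (open diamonds), with lines joining both values of a genotype. The cholesterol list lies lowest, at -1.0 in wildtype and -1.10 in knockout mice.

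In knockout mice, the same diet comparison had fold changes of the same kind, but edgeR called 1 gene. Adgrf1 fell from 8.92 ± 5.84 CPM (n = 4) on chow to 1.25 ± 1.23 CPM (n = 15) on Western diet (log2 fold change -2.83, SE 0.52, adjusted p = 0.0479), in 15 of 15 Western diet libraries. Among 24 cholesterol synthesis and uptake genes, 0 passed over all genes and 22 were lower adjusted over the list alone. Cyp51 was at 143 ± 70.8 CPM on chow and 45.4 ± 50 CPM on Western diet (-1.66, SE 0.49, adjusted p = 0.121), and Lss, lanosterol synthase, at -1.06. The list passed camera (23 of 24 negative, median -1.10, adjusted p = 5.81e-16), with an adjusted p = 0.493 with an estimated correlation. The 6 genes nearest to a call were BC030867 (-4.08), BC029722 (0.66), Gm8893 (-1.48), Tmem120a (0.51), Hnrnpa1 (-0.46) and Mir17hg (-1.05), each with an adjusted p of 0.0801.

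Another 8 lists passed camera in knockout mice, 0 of them with an estimated correlation, and 0 of their members were called over all genes. Fatty acid oxidation and PPARA targets rose as a list, with a positive fold change in 24 of 24 members but 0 of them passing by gene (median 0.46, adjusted p = 1.52e-07, and adjusted p = 0.493 with an estimated correlation), with Etfdh (0.51), Hadha (0.38) and Cpt1a, the carnitine transferase of mitochondria (0.55). Fatty acid and triglyceride synthesis rose as a list (17 of 22 positive, adjusted p = 0.00605, and adjusted p = 0.728 with an estimated correlation), with Srebf1 at 473 ± 315 and 950 ± 274 CPM (1.01, adjusted p = 0.124), Agpat2 (0.38), Scd1 (1.05) and Acaca (0.75). Fructose and glucose metabolism rose as a list (12 of 17 positive, adjusted p = 0.00408, and adjusted p = 0.493 with an estimated correlation), with 6 members higher adjusted over the list alone, among them Khk at 624 ± 202 and 889 ± 207 CPM (0.51), Tkfc (0.70) and Pcx (0.73). Lipid droplet genes rose as a list (16 of 18 positive, adjusted p = 5.42e-04, and adjusted p = 0.493 with an estimated correlation), with Cidec at 12 ± 11.1 and 39.1 ± 32 CPM (1.70), Plin5 (0.42), Cideb (0.33) and Hilpda (0.61). Erythroid markers rose as a list, all 5 members adjusted over the list alone (median 3.15, adjusted p = 8.02e-04, and adjusted p = 0.493 with an estimated correlation), with Hba-a1 at 1.55 ± 0.779 and 13.5 ± 11 CPM, Hbb-bt at 4.48, Hbb-bs at 3.35 and Alas2 at 0.35. Cell cycle genes rose as a list (19 of 21 positive, adjusted p = 6.70e-04, and adjusted p = 0.675 with an estimated correlation), with the replication helicase genes Mcm2 (0.62), Mcm4 (0.55) and Mcm5 (0.76), and Ccne1 (1.09). The acute phase list rose (23 of 24 positive, median 0.66, adjusted p = 0.00605, and adjusted p = 0.764 with an estimated correlation), with Serpina3m (0.65), Serpina3n (0.73), Crp (0.27) and Lcn2 (3.38). Sinusoidal endothelial markers fell as a list (11 of 12 negative, median -0.40, adjusted p = 6.60e-04, and adjusted p = 0.675 with an estimated correlation), with Ehd3 (-0.52), Clec4g (-0.51), Fcgr2b (-0.57) and Dnase1l3 (-0.44), and 3 members lower adjusted over the list alone. With knockout chow D left out, the acute phase and endothelial lists did not pass (both adjusted p = 0.0599), nor did fatty acid and triglyceride synthesis with knockout chow C left out (adjusted p = 0.156).

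The remaining 21 lists had adjusted p between 0.0560 and 0.889 in knockout mice, and Cd163 was at -0.72 (adjusted p = 0.446). Without the 4 libraries, edgeR called 1498 genes higher and 1159 lower on Western diet in place of 1, and Adgrf1 was among them. Leaving out 1 library gave 1408 genes without knockout chow D, 203 higher and 223 lower without knockout Western diet M and 13 without wildtype Western diet A, 1 without wildtype chow A or B or knockout Western diet H, I or O, and 0 without any of the other 31. DESeq2 called 226 genes and limma voom 804. With edgeR, 2943 genes (19.2%) had an unadjusted p under 0.05, against 2634 (17.2%) for diet in wildtype mice. The edgeR counts of 1 and 212 therefore do not show a weaker diet response in knockout mice.

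Whether the genotypes differ in their diet response was tested by the interaction. Over 15296 genes, edgeR called 0, with 285 at an unadjusted p under 0.05, and DESeq2 and limma voom each called 0. In simulated data, the interaction test recovered 12% of genes changed by 0.5 and 55% of those changed by 1 on the log2 scale. The simulation changed 200 independent genes at once, so the limit given for Western diet holds here too. The count of 0 therefore does not show that the genotypes respond alike. BC030867 had the smallest p (log2 difference -6.47, SE 1.52, adjusted p = 1.00), followed by Star (-0.81), Nat8f7 (-4.46), Gm9502 (-1.63), Smim14 (0.31) and Scx, a transcription factor of tendon cells (-1.20). Cd163 had a difference of -0.64 (SE 0.61). Of the 30 lists, 7 passed camera, and 0 of their members passed by gene, over all genes or adjusted over the list alone. Stellate cell and fibrosis genes had the more positive diet effect in knockout mice in 25 of 26 members (median 0.30, adjusted p = 6.36e-04, and adjusted p = 0.785 with an estimated correlation), led by Thbs1 (1.70), Dpt (0.97), Col4a2 (0.53) and Acta2 (0.68). The same side held for inflammatory cytokines and chemokines (median 0.58, adjusted p = 0.00964, and adjusted p = 0.785 with an estimated correlation), with the innate receptors Tlr4 (1.16) and Tlr2 (1.49), Ccl3 (2.59) and Nlrp3 (0.77). It held for recruited and lipid-associated macrophage markers (median 0.47, adjusted p = 0.0133, and adjusted p = 0.785 with an estimated correlation), with Chil3 (2.52), Mmp12 (2.55), Spp1 (0.32) and Lpl (0.60). The stress response list (median 0.27, adjusted p = 0.0235, and adjusted p = 0.785 with an estimated correlation) had Dnajb9 (0.80), Atf3 (1.15), Herpud1 (0.52) and Pdia4 (0.47). The acute phase list (median 0.22, adjusted p = 0.0276, and adjusted p = 0.972 with an estimated correlation) had Lcn2 (2.56), Lbp (0.74), Saa2 (2.18) and Saa1 (1.78). The erythroid list (median 1.41, adjusted p = 0.0390, and adjusted p = 0.785 with an estimated correlation) had Hbb-bt (2.73), Hbb-bs (1.86), Hba-a1 (1.32) and Hba-a2 (1.41). Sinusoidal endothelial markers had the more negative diet effect in knockout mice (10 of 12 members, median -0.25, adjusted p = 0.00557, and adjusted p = 0.785 with an estimated correlation), with Stab2, a scavenger receptor of these cells (-0.44), Dnase1l3 (-0.42), Clec4g (-0.29) and Ehd3 (-0.27). The other 23 lists had adjusted p between 0.0591 and 0.911.

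Several of these interaction calls rested on few libraries. With 1 library left out, the acute phase list passed in 24 of 39 fits and the erythroid list in 20, with adjusted p = 0.634 and 0.278 without wildtype chow E. The stress response list passed in 31 of 39 fits, with its highest adjusted p, 0.236, without knockout chow A. The inflammatory and recruited macrophage lists passed in 36 fits each, with their highest adjusted p without wildtype chow E (0.214) and without knockout Western diet F (0.222). The endothelial list passed in 38 fits and was lost without knockout chow D (adjusted p = 0.107). Knockout Western diet F had a mean of 3.58 log2 CPM over the recruited macrophage list, against 1.15 to 2.27 in the other 14 knockout Western diet libraries, and 4.69 over the stellate cell and fibrosis list, against 2.75 to 3.92. The stellate cell and fibrosis list passed in 39 of 39 fits. Without the 4 libraries, 0 genes and 1 list, stellate cell and fibrosis genes, passed (adjusted p = 3.08e-04, and 0 lists with an estimated correlation).

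**Figure D4:**
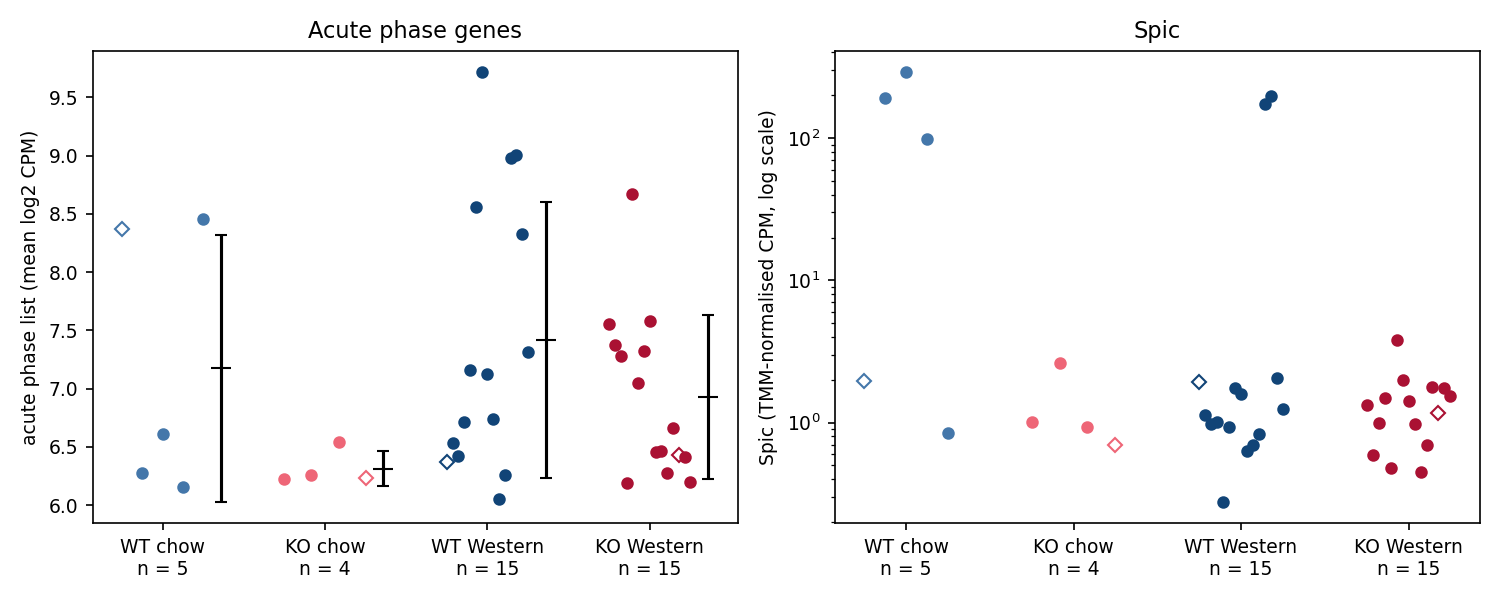
Left, the mean log2 CPM of the acute phase list in each library by group, with the group mean and SD in black. Right, the CPM of Spic in each library on a log axis, where 5 wildtype libraries lie between 98.3 and 290 CPM and the other 34 libraries between 0.278 and 3.80 CPM, and open diamonds mark the 4 libraries that stood with the other diet.

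The fold changes of the diet comparisons were correlated across genes, which are not independent replicates and give no p. Over 15296 genes, Pearson's r was 0.621 and Spearman's rho 0.602 between wildtype and knockout mice. Over the 212 genes called in wildtype or knockout mice, r was 0.941 and rho 0.959, and 212 of 212 had the same sign. Adgrf1 was the 1 gene called in both genotypes, against 0.00615 for independent lists of that direction. Without the 4 libraries, 902 genes were called on the same side in both genotypes, 481 of them higher, against 63.9 higher and 51.0 lower for independent lists. Over all genes, r was then 0.727 and rho 0.674. Without a filter on low counts, r was 0.0921 over all genes.

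Genes beside Cd163 were read for effects of the targeted allele. Within 1 Mb of Cd163 in GRCm38, 105 other genes are annotated, and 43 of them were tested. By edgeR, 0 were called in either diet, and the smallest p adjusted over the list alone was 0.258 on Western diet and 0.915 on chow. At an unadjusted p under 0.05, there were 4 on Western diet and 0 on chow. The 4 were C1ra (-0.19) and C1s1 (-0.13), which encode complement proteases, Gpr162 (-0.40) and Ptpn6, a phosphatase of blood cells (0.15). DESeq2, and edgeR with no filter on low counts, each called 2 genes near Cd163 on Western diet, 1700013D24Rik and Gm44007, which the filter had removed and which were chosen here after their values were seen. 1700013D24Rik (ENSMUSG00000079346), the next gene after Cd163 in GRCm38 order, had 94 counts over 18 of 19 knockout libraries and 0 counts in 20 wildtype libraries. That is 0.327 CPM in knockout mice (exact Poisson 95% interval 0.264 to 0.400), and at most 0.0121 CPM in wildtype mice. Gm44007 (ENSMUSG00000108026), 4 genes away, had 56 counts in 16 knockout libraries and 1 count in 1 wildtype library.

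Across the 5 comparisons, 33 of 150 list tests passed with the preset correlation and 0 with an estimated correlation. The median, mean and test differed in sign in 18 list tests, 0 of them among the 33. By camera, 14 of the 30 lists passed in no comparison. The resident Kupffer cell markers, among which CD163 protein is normally found, had their lowest adjusted p, 0.129, in the diet comparison of knockout mice. The haemoglobin, haem and iron list, which holds the partners of CD163 function such as Hp and Hmox1, had its lowest adjusted p at 0.473, and scavenger and lipoprotein receptors at 0.380. Hp, haptoglobin, was at 5764 ± 3684 CPM in wildtype and 4326 ± 1793 CPM in knockout mice on Western diet (log2 fold change -0.41, SE 0.26, adjusted p = 0.943), and Hmox1, haem oxygenase, at 22.4 ± 12.3 and 22.5 ± 10.7 CPM (0.01, SE 0.23). For markers of other immune cells the lowest adjusted p was 0.445 (neutrophils), 0.473 (T and NK cells) and 0.0954 (B and plasma cells). It was 0.0752 for cholangiocyte markers, 0.324 for adipose tissue markers and 0.0958 for pancreas markers, of which 1 gene was measured. It was 0.265 for male-biased and 0.435 for female-biased liver genes, 0.0870 for bile acid genes, 0.180 for the NRF2 antioxidant response and 0.749 for immediate early genes.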

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

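The tests of the 4 libraries, of Spic and of the genes beside Cd163 were chosen after their results were seen, whereas those of other splits of the samples were set before.

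In 4 libraries the diet genes stood with the other diet, while Cd163 fitted their genotype labels. An exchange of diet labels within each genotype, of chow A with Western diet A in wildtype and of chow D with Western diet M in knockout mice, is a hypothesis without a test of its own, since all 4 were picked for lying nearer the other diet's mean and a count of 4 restates that. RNA of both diets mixed in these libraries is argued against, since the largest distance of the 4 from the other diet's mean was 0.109 of the distance between the diets. Western diet mice that did not respond could account for the Western diet libraries alone, and 2 chow libraries lay nearer the Western diet mean. An exchange of feeding, samples or labels stays open, and the data at hand do not say which.

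Spic was at 98.3 to 290 CPM in wildtype chow B, C and D and wildtype Western diet L and M, and at 0.278 to 3.80 CPM in the other 34 libraries, a gap of 25.9-fold. Cells of a type absent from the other livers would bring further genes. Besides Spic, 0 genes had all 5 libraries at more than 2 times the highest of the other 34. This rule can hardly detect more cells of a type that every liver holds, such as Kupffer cells. Their marker mean without Spic was 4.08 to 4.90 log2 CPM in the 5 libraries and 3.44 to 5.31 in the other 34. Low Spic does not need loss of Cd163, since 15 of 20 wildtype libraries lay at or below the highest knockout library. That count follows from the choice of the 5 libraries. It cannot say whether high Spic needs Cd163. All 5 high libraries were wildtype, and all 19 knockout libraries lay at or below 3.80 CPM. Transcription of the whole region is argued against, since 0 of 14 tested neighbours followed. What sets Spic in these 5 mice may be biological or technical and stays open, and the library numbers of B, C and D follow each other, as do those of L and M.

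Close to Cd163, 1700013D24Rik had 94 counts in knockout and 0 in wildtype libraries, and Gm44007 had 56 and 1. Depth does not account for it, since the exact 95% upper limit of the wildtype rate of 1700013D24Rik was 0.0121 CPM, below the knockout interval of 0.264 to 0.400 CPM. Between genotypes, the exact permutation p was 0.00794 on chow for each gene, the smallest possible, and the permutation p on Western diet, over absolute differences in 100000 resamples, was 1e-05 (the smallest possible for absolute differences) and 4e-05. A candidate explanation is transcription at or through the targeted allele, since the 2 genes called without a filter besides Cd163 both lay among the 75 genes of its 1 Mb window, of 36318 genes (Fisher's exact p, one-sided, 4.21e-06). The window was tested for the genes that showed the pattern, so this is a hypothesis.

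Within the chow groups, 278 sets of values were searched for a library far from the rest, measured as its gap to the nearest library divided by the group's range. Chance gives about 1 in 20, or 13.9, and 34 were found, 23 of them in wildtype chow A and knockout chow D. Wildtype chow A and knockout chow D had already been picked for standing with the other diet. The sets include the cholesterol list and genes named in the diet comparisons, such as Cyp51 and Msmo1. An excess in these libraries was therefore nearly fixed in advance. The sets also share libraries and genes, so 34 against 13.9 is not a test of chance. Wildtype chow A was lowest for the cholesterol list (0.923), the endothelial list (0.726), the NRF2 list (0.851), Csad (0.756), Adgrf1 (0.750), Nsdhl (0.752), Cyp51 (0.940), Msmo1 (0.865), Mvk (0.926), Srebf2 (0.874), Cyp3a11 (0.827) and Lss (0.779), and highest for the interferon list (0.768), Tkfc (0.728) and Etfdh (0.718). Knockout chow D was lowest for Adgrf1 (0.861) and Cyp51 (0.965), and highest for Apoa4 (0.853), Abcb4 (0.865), Cpt1a (0.921), Khk (0.916), Cidec (0.906) and Mmp12 (0.833). Knockout chow A was lowest for Saa1 (0.920), 4931406P16Rik (0.856), Bglap3 (0.925) and Stab2 (0.986). Knockout chow C was highest for the acute phase list (0.902) and lowest for Nat8f7 (0.871). Wildtype chow D was highest for Gm9502 (0.752) and lowest for Herpud1 (0.748). Wildtype chow E was highest for Psmb8 (0.884), B for Cideb (0.738) and C for Mcm2 (0.851).

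The diet effect differed between genotypes, by camera on the interaction, in 7 lists: stellate cell and fibrosis genes (adjusted p = 6.36e-04), endothelial markers (0.00557), inflammatory cytokines and chemokines (0.00964), recruited macrophage markers (0.0133), the stress response (0.0235), the acute phase response (0.0276) and erythroid markers (0.0390). With an estimated correlation, 0 of the 7 passed.

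For each count, 100 splits of the same libraries were compared, the real one included. The count of 212 genes between diets in wildtype mice was reached by the real split alone (highest other 5). Chance is unlikely for that count but not excluded, since 100 splits cannot give a share below 1 in 100. The count of 1 gene between genotypes was reached by 2 splits on Western diet (highest other 1) and by 11 on chow (highest other 5). That gene is Cd163 in both diets, and a count of genes does not measure how far Cd163 separates the genotypes. Chance cannot be excluded for the count on chow, or for 1 gene between diets in knockout mice (20 splits, highest other 31). For the interaction, the real count of 0 is reached by all 100 splits whatever the data (highest other 2), so the splits say nothing on chance there.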

How the results depend on the processing

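The fit without 4 libraries, wildtype Western diet L and M as 1 library and the permutation of list means were chosen after the data were seen. Over 174 gene results and 33 list results, each taken in the settings that measured it, 8282 of 8286 gene values and 1675 of 1676 list values kept their direction. Most of these settings leave out 1 library of the reported fit, and the results were picked from that fit. Kept direction was therefore nearly fixed in advance. A call was lost in 444 gene values and 239 list values and gained in 186 gene values. Cd163 kept its call on Western diet in all settings, from -4.59 to -4.40 with 1 library left out, and on chow (-4.01 to -3.67) except with limma voom (-3.81).

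Counts of genes, in the order genotype on Western diet, diet in wildtype and diet in knockout mice, were 3, 44 and 0 without a filter, where more genes are tested, and 4, 512 and 226 with DESeq2. With limma voom, genotype on chow gave 0 and the diet comparisons 1020 and 804. The diet comparisons gave 50 and 0 with the replicate block, 0 and 0 with the library number, 116 and 0 with L and M summed and 1339 and 2657 without the 4 libraries, and the knockout comparison 0 with only the groups compared. Leaving out 1 library gave 1 to 1 and 1 to 1 for genotype on Western diet and on chow, 0 to 556 and 0 to 1408 for diet, and 0 to 0 for the interaction. Genes near Cd163 on Western diet were 2 without a filter and 2 with DESeq2 and 0 to 0 with a library left out. Except for the filter, the cause was not tested.

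Lists, in the order genotype on Western diet, genotype on chow, diet in wildtype, diet in knockout and interaction, were 0, 0, 0, 0 and 0 with an estimated correlation, 0, 0, 2, 0 and 0 with fry and 0, 0, 0 and 0 by permutation (no interaction value). Without the 4 libraries, camera passed 5 on Western diet, 2 on chow and 1 in the interaction, an estimated correlation 0, 0, 1, 1 and 0, fry 0, 0, 4, 8 and 0, and permutation 0, 0, 3 and 4. The list passing with an estimated correlation was cholesterol synthesis, with adjusted p = 9.61e-05 in wildtype and 0.00243 in knockout mice. Without a filter, 14 passed for diet in knockout mice and 4 in the interaction. The replicate block gave 1 in the interaction, the library number 6 for genotype on Western diet, and voom 5 there and 3 in the interaction. Library number and genotype nearly coincide on Western diet, so that setting can hardly separate them. Leaving out 1 library gave 3 to 6, 2 to 5, 7 to 11, 7 to 12 and 3 to 9.

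Agreement between genotypes over all genes was r = 0.0921 and rho = 0.160 without a filter and 0.158 and 0.201 with DESeq2. Over called genes it was 0.941 and 0.959. The setting without a filter changed the filter alone, so its lower values come from letting in genes with low counts. DESeq2 was also run on unfiltered counts, and the part of its other differences was not tested. With a library left out, r ran from 0.522 to 0.667 and rho from 0.496 to 0.638. Genes called in both were 0 without a filter, with the block, the library number, only the groups compared or L and M summed, 379 with voom, 98 with DESeq2, 902 without the 4 libraries and 0 to 215 with a library left out.

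Values that turned direction were the endothelial list between genotypes on Western diet with the library number (adjusted p = 0.847), Cd163 between diets in wildtype mice without wildtype chow A (0.08), without B (0.11) and without the 4 libraries (0.11), with a range of -0.23 to 0.11 over libraries left out, and Hba-a2 in the interaction without wildtype chow E (-0.0850), with a range of -0.0850 to 1.82. Depth limits genes such as 1700013D24Rik, with at most 12 counts per library.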

Other observations

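The genes and values here were chosen after the data were seen, and the 4 libraries left out were picked by their diet genes, so counts without them are not independent evidence of a diet effect.

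Without those 4 libraries, the diet genes had larger fold changes in both genotypes. Sqle, squalene epoxidase of cholesterol synthesis, fell in wildtype (log2 fold change -4.25) and knockout mice (-4.52) (edgeR adjusted p = 2.00e-11 and 3.41e-11), against an adjusted p of 0.0562 and 0.124 with all libraries. Hamp, which encodes the iron hormone hepcidin, fell too (-1.77 and -2.62, adjusted p = 7.34e-04 and 7.79e-06), from 877 ± 94.6 CPM in all wildtype chow libraries to 339 ± 305 CPM in all wildtype Western diet libraries. Enho, the adropin gene, fell (-2.48 and -3.67), and Smpd3, Ntrk2 and Mfsd2a, a lipid transporter, rose by 3.19 and 3.79, 4.29 and 4.84, and 2.88 and 2.55. Cfd, adipsin, rose by 5.66 and 6.00 (SE 1.65 and 1.92). It was at 35.6 ± 50.1 CPM in all wildtype and 46.3 ± 51.7 CPM in all knockout Western diet libraries. With all libraries, its fold changes were 4.33 and 2.42 and did not pass (edgeR adjusted p = 0.113 and 0.303). Lpl rose in knockout mice (1.27, adjusted p = 0.00879) and was at 0.59 in wildtype mice (adjusted p = 0.188), with an interaction of 0.68 that did not pass (adjusted p = 0.999).

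Some genes varied between mice of the same group. Saa1 ranged from 34.2 CPM in wildtype Western diet K to 9315 CPM in G, and Mt1 from 2.69 CPM in I to 305 CPM in G. Hba-a1 ranged from 0.867 CPM in knockout Western diet L to 34 CPM in I. BC030867 was at 8.05 and 7.29 CPM in knockout chow A and C and at 7.21 CPM in wildtype Western diet I, and at or below 0.797 CPM in every other library. Trat1, a T cell adaptor, was at 4.89, 6.13 and 3.52 CPM in wildtype Western diet G, L and M.

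No further hypothesis was tested.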
